A study of Homo sapiens with 25 samples.

How the data were processed

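Total RNA from 25 tumour biopsies was extracted with a Qiagen AllPrep kit, per the labels' protocols, and sequenced. The authors deposited 1 table of 60338 genes by 25 libraries. Its header names no unit; the values are not whole and their totals differ between libraries, so they were taken as FPKM, the abundance that StringTie reports, as the authors deposited it. Trim Galore, HISAT and StringTie with build hg38 are named in the submitters' processing notes. Their versions, the annotation release and the strand setting are not given in the sources used here. Read depth cannot be recovered from these FPKM values, so no counting interval is given. Reads of near-identical genes, such as immunoglobulin constant regions, HLA genes and snoRNA copies, can be split among them by an abundance estimate.

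Genes of chromosome Y with XIST and TSIX (568) and genes with a missing value (16) were left out, which left 59754. Coordinates came from GENCODE 29 by Ensembl ID, which matched 56813 genes. Libraries were grouped by tumour type and time point from the labels. The labels give the same biopsy number to both libraries of a patient, which made 9 pairs, and name no batch. In the 5 prostate pairs the deviations of the 2 libraries from their group means had correlations between -0.16 and 0.55 with a median of 0.20, against -0.06 for libraries of different patients. Deviations from a group mean cancel out over its libraries, so the value for different patients is tied to that for the same patient and is no independent reference. The highest correlation between any 2 libraries was 0.959, so none were counted as duplicates.

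Each gene comparison used limma 3.58.1 in R 4.3.3 with trended, robust empirical Bayes on log2(FPKM + 1). Genes with at least 1 FPKM in at least 5 of the fitted libraries were tested, and the Benjamini-Hochberg adjusted p threshold was 0.05. The patient was a block in the paired comparisons. The gene list score was the mean of log2(FPKM + 1) over measured members, and lists with fewer than 4 were not tested. List tests were two-sided and exact: 512 sign flips for 9 pairs, 1716 splits for 6 against 7 libraries and 126 splits for 5 against 4 pairs. Correlations used exact permutations, or 100000 resamples over 16 libraries. Their scores used the members past the filter over all 25 libraries. The 36 lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 12 smallest p per direction among approved symbols past the threshold with a fold of at least 2, or 5 values where fewer than 5 passed, with 21 fixed genes and up to 4 members of each list described. Immunoglobulin variable segments were not named, and 1 gene the rule took is not reported here. Of the fixed genes, those not named in a comparison were below the filter or did not pass.

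The pipeline was tested on simulated data with 50 changed genes per fold size. Noise was drawn for each gene independently from its residual SD, so variation shared between genes was not simulated. Recovery in the real libraries may therefore differ from the shares below. In the prostate pairs (14209 genes) it recovered 2% of 2-fold, 44% of 4-fold, 80% of 8-fold and 88% of 16-fold changes. In all pairs (17676 genes) it recovered 22%, 76%, 94% and 100% of those sizes. In the pancreatic against prostate comparison (16084 genes) it recovered 14%, 76%, 96% and 96%. In the test of the difference between tumour types (17676 genes) it recovered 0%, 8%, 46% and 72%. Unchanged genes called were 5 in the prostate pairs, 6 in all pairs, 12 between pancreatic and prostate and 3 for the difference. Alternatives were a pseudocount of 0.1, no filter, quantile normalization, array weights, empirical Bayes without trend, no pairing, the patient as a random effect, leaving out pairs or libraries, centred list scores and camera with a preset correlation of 0.01 or an estimated one. Scaling to the protein-coding sum, leaving out doubted libraries and other choices of immunoglobulin genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.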

Results

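RNA was sequenced from tumour biopsies of 16 patients given evofosfamide, a prodrug activated in hypoxic tissue, together with ipilimumab, an antibody to the T cell checkpoint receptor CTLA4. The 25 libraries comprised 16 biopsies taken before treatment and 9 taken after 2 doses of each drug. Prostate tumours gave 7 libraries before and 5 on treatment, and pancreatic tumours gave 6 and 2. The remaining libraries came from melanoma and head and neck tumours. The same patient gave both libraries in 9 pairs, of which 5 were prostate and 4 were of the other tumour types. Expression was deposited as FPKM, so the read depth behind each value is unknown. Protein-coding nuclear genes held between 7.73% and 52.0% of a library's FPKM, and between 8713 and 12762 of them reached 1 FPKM. Fold changes below are on the log2(FPKM + 1) scale, which understates the change of low genes.

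Marker genes were examined first, because they bear on the labels. KLK3, which encodes prostate-specific antigen, was below 1 FPKM in 4 of the 12 libraries labelled prostate, 3 of them on treatment. HOXB13, a prostate transcription factor, was below 1 FPKM in 2 of the 12, both on treatment. ALB, which encodes serum albumin and is made by hepatocytes, reached at least 100 FPKM in 3 of the 6 pancreatic and 1 of the 7 prostate libraries before treatment, and in 2 of the 5 prostate libraries on treatment. By a check on few marker genes, 1 of the 25 libraries did not match its group's label. The prostate-labelled libraries low in KLK3 or HOXB13 are not part of this count. The check did not cover the markers of every tumour type or test every label, so the other libraries were not shown to match theirs.

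The first comparison asked what changed on treatment within prostate tumours. Immunoglobulin genes were higher on treatment in the 5 prostate pairs. Among these pairs, 1 library before treatment had the lowest number of protein-coding nuclear genes of at least 1 FPKM, 8713. IGKC, the constant region of the kappa light chain, averaged 20.1 ± 31.7 FPKM (SD, n = 5) before and 635 ± 678 on treatment, a log2 fold change of 5.44 ± 0.78 (SE, limma adjusted p = 0.0267). IGHG1, a constant region of the IgG heavy chain, averaged 21.7 ± 32.6 FPKM before and 226 ± 219 on treatment (log2 fold change 4.24 ± 0.43, limma adjusted p = 0.00587). IGHM, the IgM constant region, rose by 2.71 ± 0.40 (limma adjusted p = 0.0314), and all of these were higher in 5 of 5 pairs. The heavy chain genes lie on chromosome 14 (IGHG1 at 105736343 to 105743071, hg38 coordinates from GENCODE 29), the kappa gene on chromosome 2 (88857161 to 88857683) and the lambda genes on chromosome 22 (IGLC2 at 22900976 to 22901437).

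In all, limma called 37 of 14209 genes in the prostate pairs, 37 higher and 0 lower, and 905 genes had an unadjusted p under 0.05. Of the 37, 35 were annotated as immunoglobulin genes, a class with 81 tested members. The other 2 were IGLL5, which overlaps the lambda constant region gene IGLC1, and RP11-731F5.2, named after its value was seen. RP11-731F5.2 is a noncoding RNA gene on chromosome 14 that lies between the heavy chain genes IGHG2 and IGHGP. IGHG2, IGHG3, IGHG4 and the pseudogene IGHGP rose by 3.84 ± 0.36, 4.13 ± 0.42, 3.66 ± 0.35 and 3.11 ± 0.34 (SE). IGLC1, IGLC2, IGLC3, IGLC7 and IGLL5 rose by 4.64 ± 0.62, 4.30 ± 0.52, 4.24 ± 0.55, 2.77 ± 0.35 and 3.94 ± 0.54. The median change of all genes was 0.17, and -0.29 with libraries scaled to 1 protein-coding sum, under which IGKC and IGHG1 were at 4.89 and 3.76. With quantile normalization IGHG1 passed (3.84) and IGKC, at 5.20, did not (limma adjusted p = 0.067). The IgG heavy chain genes are near-identical copies that can share reads, as are the lambda genes, so the split within each of these sets is uncertain. No gene was called without the pairing, where 735 genes had an unadjusted p under 0.05, or without a filter on low values, where 1279 did. No gene was called in the 3 pairs left without the 2 whose on-treatment library had HOXB13 below 1 FPKM (350 at an unadjusted p under 0.05), where IGHG1 was at 3.90 and the plasma cell list at 2.85 ± 0.36 (SD, n = 3, 3 of 3 higher), and leaving out 1 pair at a time gave 12 to 26 calls.

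**Figure D1:**
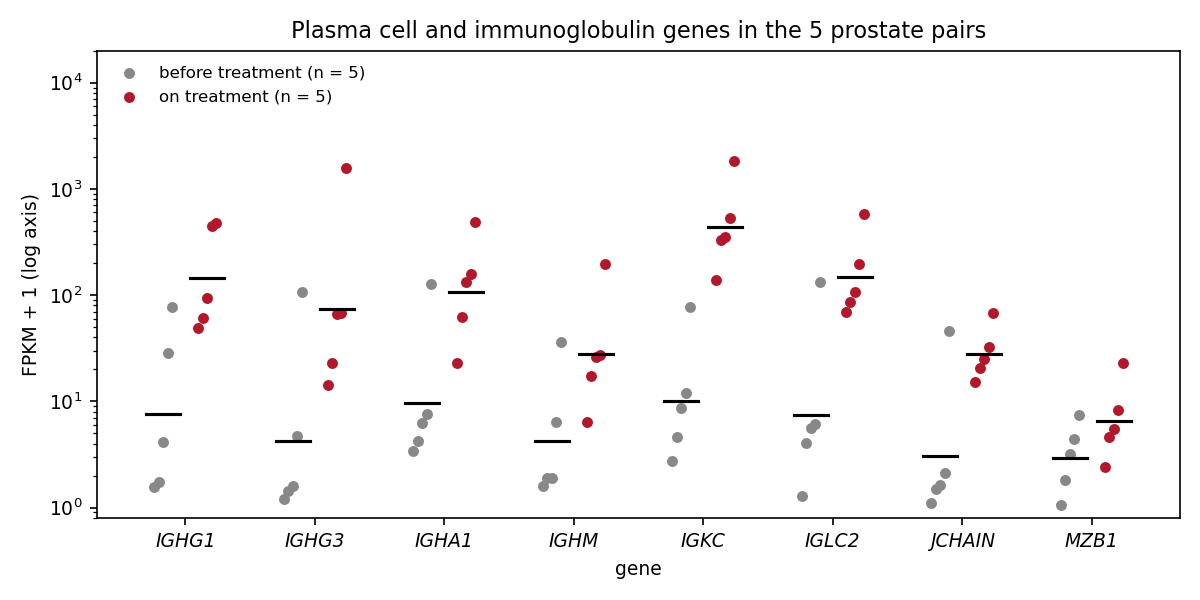
FPKM + 1 on a log axis for 8 immunoglobulin and plasma cell genes in the 5 prostate pairs, with 1 point per library before (grey) and on (red) treatment and bars at the mean of the log2 values. IGKC averaged 20.1 FPKM before and 635 on treatment, while MZB1 averaged 2.59 and 7.81 and did not pass the test.

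The plasma cell list, 11 markers of antibody-secreting cells of which 7 were measured, had a score change of 2.98 ± 0.40 (SD over the 5 prostate pairs, log2 scale) and was higher in 5 of 5 pairs. Of its 7 measured members 4 rose over all genes tested, and 5 when adjusted over the list alone. The 4 were the immunoglobulin genes IGHG1, IGKC, IGHM and IGHA1, already among the genes called above, so the list score largely restates that result. The fifth was JCHAIN, the joining chain of IgA and IgM (log2 fold change 3.21 ± 0.53, limma adjusted p = 0.0539 over all genes). The camera adjusted p of the list was 0.036 with an estimated correlation. Without the filter on low values the list had a change of 2.16 ± 0.47 (SD, 5 of 5 pairs higher). MZB1, a plasma cell chaperone, had a log2 fold change of 1.17 ± 0.62 and PIM2 one of 0.62 ± 0.43. With 5 pairs the smallest p that sign flips can give is 0.0625, so no list could pass that test in the prostate pairs alone and the scores are given as values.

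Interferon gamma and T cell genes had positive changes in the prostate pairs but were not called over all genes. The interferon gamma response list had a change of 1.34 ± 0.50 (SD, n = 5 pairs), with 5 of 5 pairs higher. Of its 13 measured members 0 were called over all genes and 10 were higher when adjusted over the list alone. They included the guanylate-binding protein genes GBP5 (1.5 ± 0.35) and GBP4 (1.40 ± 0.34), the T cell-attracting chemokine gene CXCL10 (2.03 ± 0.57) and the transcription factor gene IRF1 (1.38 ± 0.39, SE). limma's camera test gave the list an adjusted p = 0.0999 with an estimated correlation. The T cell list had a change of 1.43 ± 1.0 (SD), with 5 of 5 pairs higher; 4 of its 14 members passed the filter on low values and 4 of those 4 were higher when adjusted over the list alone. Over the 14 members without the filter the list had a change of 0.84 ± 0.79 (5 of 5 higher). CD2, CD3D and CD3E, which encode T cell surface proteins, had log2 fold changes of 1.61 ± 0.37, 1.59 ± 0.42 and 1.51 ± 0.40. The CD8 and cytotoxic list had a change of 1.15 ± 0.81 (SD, 4 of 5 pairs higher), and 6 of its 8 measured members were higher when adjusted over the list alone, led by the granzyme gene GZMA (1.74 ± 0.33, limma adjusted p = 0.0994 over all genes) and by CD8A (1.11 ± 0.29). For the T cell and the CD8 lists camera gave an adjusted p = 0.368 with an estimated correlation. The hepatocyte score, over a filter shared with the other tumour types, had a change of 3.04 ± 4.88 (SD, 3 of 5 pairs higher) in the same pairs, and the prostate epithelium score one of -0.55 ± 3.35 (2 of 5 higher).

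Other lists gave these values in the 5 prostate pairs. The lymphoid aggregate chemokine list had a change of 1.40 ± 1.37 (SD), with CCL19 at 2.65 ± 0.62 and CCL21 at 2.25 ± 0.68, both higher when adjusted over the list alone, and one of 0.92 ± 0.94 over its 10 members without the filter. The HLA class I presentation list had a change of 1.19 ± 0.76, with HLA-B at 1.58 ± 0.45 higher when adjusted over the list alone; HLA genes share reads with one another, so their split is uncertain. Of the 12 members of the HLA list 7 passed the filter, and over the 12 without it the list was at 0.80 ± 0.45 (5 of 5 higher). Its antigen-processing members TAP1, TAP2, PSMB8 and PSMB9, named after their values were seen, averaged 0.595, 0.594, 0.702 and 0.162 FPKM on treatment. The HLA list was at 0.71 ± 0.50 with protein-coding sum scaling and at 0.69 ± 0.29 (n = 3) without the pairs with HOXB13 below 1. The macrophage list had a change of 1.36 ± 1.85 and CD163, a scavenger receptor gene, one of 2.13 ± 0.81, with 0 of 12 members called, and the list was at 0.26 ± 1.51 (n = 3) without the pairs with HOXB13 below 1. The HIF hypoxia target list had a change of -0.38 ± 0.88, with 2 of 5 pairs higher and 0 of 25 members called. It was at -0.62 with quantile normalization and -0.87 with protein-coding sum scaling, each with 1 of 5 pairs higher. VEGFA, the angiogenic factor, was at -1.10 ± 0.44 (limma adjusted p = 0.741), and EGLN3, an oxygen-sensing hydroxylase gene, at -1.77 ± 0.52 (limma adjusted p = 0.584). The lowest p among genes that were lower belonged to REG4, a secreted lectin of gut epithelium (-1.76 ± 0.32, limma adjusted p = 0.087), MIR6769A (-1.45 ± 0.29), TTC6 (-1.37 ± 0.31), SNORD50 (-1.35 ± 0.31) and MIR612 (-1.78 ± 0.44), none of which passed. CTLA4, the target of ipilimumab, lay below the filter and averaged 0.111 ± 0.139 FPKM before and 0.576 ± 0.772 on treatment (SD, n = 5), and FOXP3, the regulatory T cell factor, averaged 0.0856 ± 0.0298 and 0.244 ± 0.174. POR, a reductase that activates evofosfamide, was at 1.32 ± 0.47 (SE, limma adjusted p = 0.728).

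The second comparison asked what changed on treatment over all 9 pairs. limma called 0 of 17676 genes, and 269 had an unadjusted p under 0.05. The smallest p among genes that were higher belonged to MAPRE3 (log2 fold change 1.08 ± 0.27, SE), the mitochondrial ribosomal RNA gene MT-RNR1 (1.39 ± 0.35), HS1BP3 (1.23 ± 0.31), the pseudogene ATP5G2P4 (0.65 ± 0.17) and DCXR (0.91 ± 0.25), and among genes that were lower to TTC6 (-0.83 ± 0.25), RPL23AP63 (-0.51 ± 0.17), RNU4ATAC12P (-0.65 ± 0.22), MIR4292 (-1.07 ± 0.37) and MIR3680-2 (-0.56 ± 0.19); none passed. CXCL9 was at 1.35 ± 0.74 and CXCL10 at 1.24 ± 0.72, each higher in 7 of 9 pairs, CD8A at 0.84 ± 0.46 and CD3E at 0.95 ± 0.49. The immune checkpoint genes PDCD1 and CD274 were at 0.26 ± 0.28 and 0.37 ± 0.25. The proliferation marker MKI67 was at 0.00 ± 0.40, and the hypoxia targets VEGFA and SLC2A1 at -0.66 ± 0.33 and -0.20 ± 0.67.

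None of 25 gene lists changed over the 9 pairs in two-sided exact sign-flip permutation tests, in which the smallest possible p was 0.00391 and 0 lists had an unadjusted p under 0.05. The lowest p was that of the CD8 and cytotoxic list, with a change of 0.73 ± 1.33 (SD, n = 9, 6 of 9 pairs higher, exact p = 0.133, adjusted p = 0.937). The interferon gamma response list had a change of 0.71 ± 1.42 (7 of 9 pairs higher, exact p = 0.168), the oxidative phosphorylation list one of 0.40 ± 0.81 (7 of 9, exact p = 0.176) and the plasma cell list one of 1.11 ± 2.47 (6 of 9, exact p = 0.195). The HIF hypoxia target list had a change of -0.07 ± 0.87 (4 of 9, exact p = 0.816) and the T cell list one of 0.49 ± 1.33 (6 of 9, exact p = 0.301).

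The third comparison set the change in the 5 prostate pairs against that in the 4 other pairs. limma called 0 of 17676 genes, with 877 at an unadjusted p under 0.05. IGHG2 had a change of 3.84 in the prostate pairs and of -1.71 in the others, a difference of 5.55 ± 1.27 (SE, limma adjusted p = 0.805). KANK1, PEG10, BCORL1 and DENND5B had differences of 2.62 ± 0.51, 2.37 ± 0.49, 1.92 ± 0.43 and 2.04 ± 0.46, and the matrix genes COL10A1 and COMP had differences of -2.96 ± 0.66 and -2.13 ± 0.57, as did MIR612 (-3.29 ± 0.76), CDKN2B (-1.51 ± 0.39) and NDUFA4L2 (-1.96 ± 0.52); none passed. The plasma cell list had a change of 2.54 ± 0.46 (SD, n = 5) in the prostate pairs and of -0.68 ± 2.88 (SD, n = 4) in the others (two-sided exact permutation p = 0.0476, adjusted p = 0.645 over 25 lists, smallest possible p 0.00794). Here 9 of its members passed the filter, run over all pairs, against 7 in the prostate pairs alone, where the change was 2.98. The rise of immunoglobulin genes in the prostate pairs was therefore not shown to differ from the other tumour types.

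**Figure D2:**
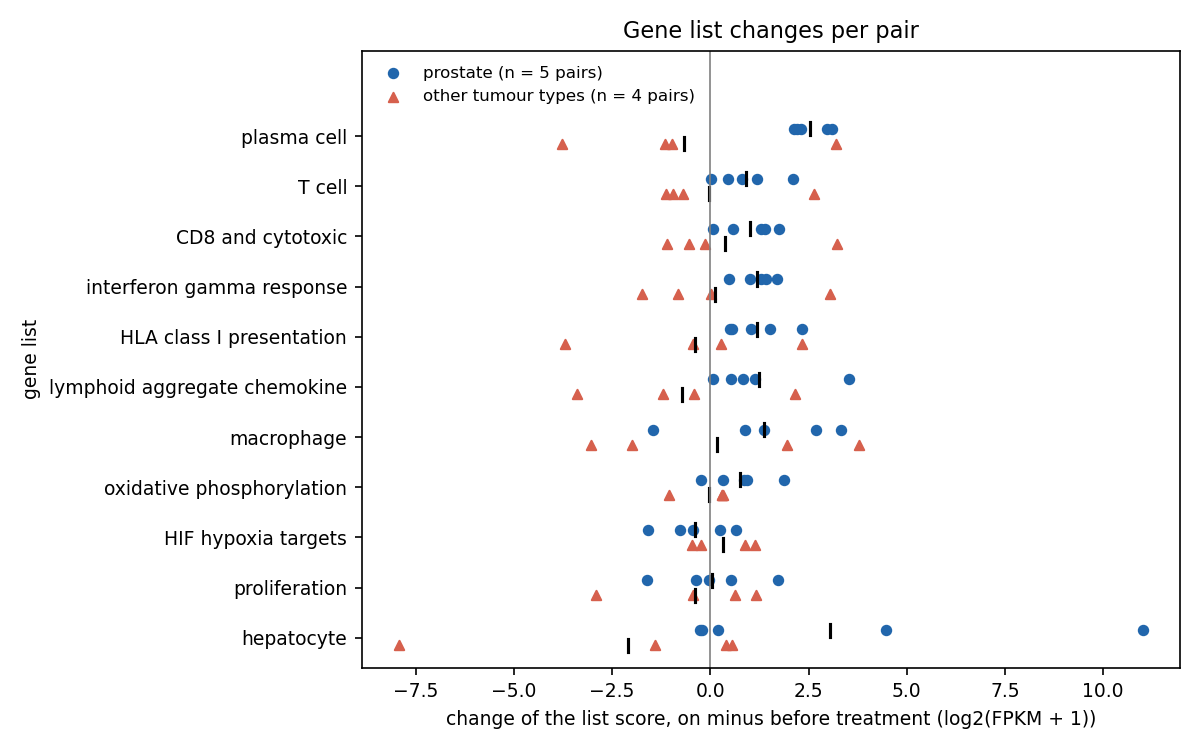
Change of 11 list scores, on minus before treatment in log2(FPKM + 1), with 1 point per pair for the 5 prostate pairs (blue circles) and the 4 other pairs (red triangles) and black bars at the group means. The plasma cell score averaged 2.54 in the prostate pairs and -0.68 in the others, and no list passed the test. Scores used the members past the filter over all pairs, so some differ from those given for the prostate pairs alone.

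The fourth comparison set the 6 pancreatic against the 7 prostate biopsies before treatment. HNF4A, a transcription factor of gut, liver and pancreas, averaged 24.1 ± 18.2 FPKM (SD) in the pancreatic and 0.908 ± 2.28 in the prostate libraries (log2 fold change 3.87 ± 0.53, SE, limma adjusted p = 0.00366). HOXB13 averaged 1.32 ± 1.79 and 28.3 ± 18.8 FPKM (-3.71 ± 0.52, limma adjusted p = 0.00366). Also higher in the pancreatic libraries were TMEM176A (3.75 ± 0.42), PTPRH (3.30 ± 0.41), the brush border genes USH1C (3.57 ± 0.46) and ANKS4B (2.03 ± 0.29), PAPSS2 (2.85 ± 0.39), FGD4 (2.72 ± 0.38), CLIC6 (1.79 ± 0.25), the neutrophil-attracting chemokine gene CXCL2 (2.71 ± 0.40), the adhesion molecule gene CEACAM1 (3.31 ± 0.48), the decoy receptor gene IL1R2 (2.46 ± 0.36) and VOPP1 (2.93 ± 0.44). Higher in the prostate libraries were HOXA9 (-1.86 ± 0.30), the noncoding RNA genes DRAIC (-1.92 ± 0.36) and LINC00665 (-1.80 ± 0.39), DLX1 (-2.73 ± 0.55), TBX1 (-1.94 ± 0.41), CLDN8 (-1.12 ± 0.24) and 4 genes of an imprinted region of chromosome 15, SNURF (-2.02 ± 0.39), SNORD64 (-2.92 ± 0.58), SNORD116-4 (-2.38 ± 0.47) and SNORD116-2 (-1.74 ± 0.38). Of the 31 tested genes of that region, 28 were lower by more than 1 in the pancreatic libraries. Short RNAs held 50.3 ± 15.7% (SD) of FPKM in the pancreatic and 64.2 ± 15.6% in the prostate libraries, and the 865 tested short RNAs outside the region had a median log2 fold change of -0.27.

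limma called 167 of 16084 genes, 142 higher in the pancreatic libraries and 25 lower. Protein-coding nuclear genes held 36.6 ± 15.1% (SD) of FPKM in the pancreatic and 19.5 ± 8.55% in the prostate libraries, and 12045 ± 591 and 10805 ± 987 protein-coding genes reached 1 FPKM. The median log2 fold change of all tested genes was 0.30, and it was -0.21 when libraries were scaled to the same protein-coding sum. That scaling gave 32 genes higher and 30 lower, and quantile normalization gave 33 and 23. Without the libraries with ALB of at least 100 FPKM 19 genes were called, and HNF4A (3.65, limma adjusted p = 0.00735) and HOXB13 (-3.86, limma adjusted p = 0.0369) passed. The count fell to 11 without the filter on low values and to 2 when the on-treatment libraries were added with the patient as a random effect. Array weights gave 370, and leaving out 1 library at a time gave 29 to 325.

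**Figure D3:**
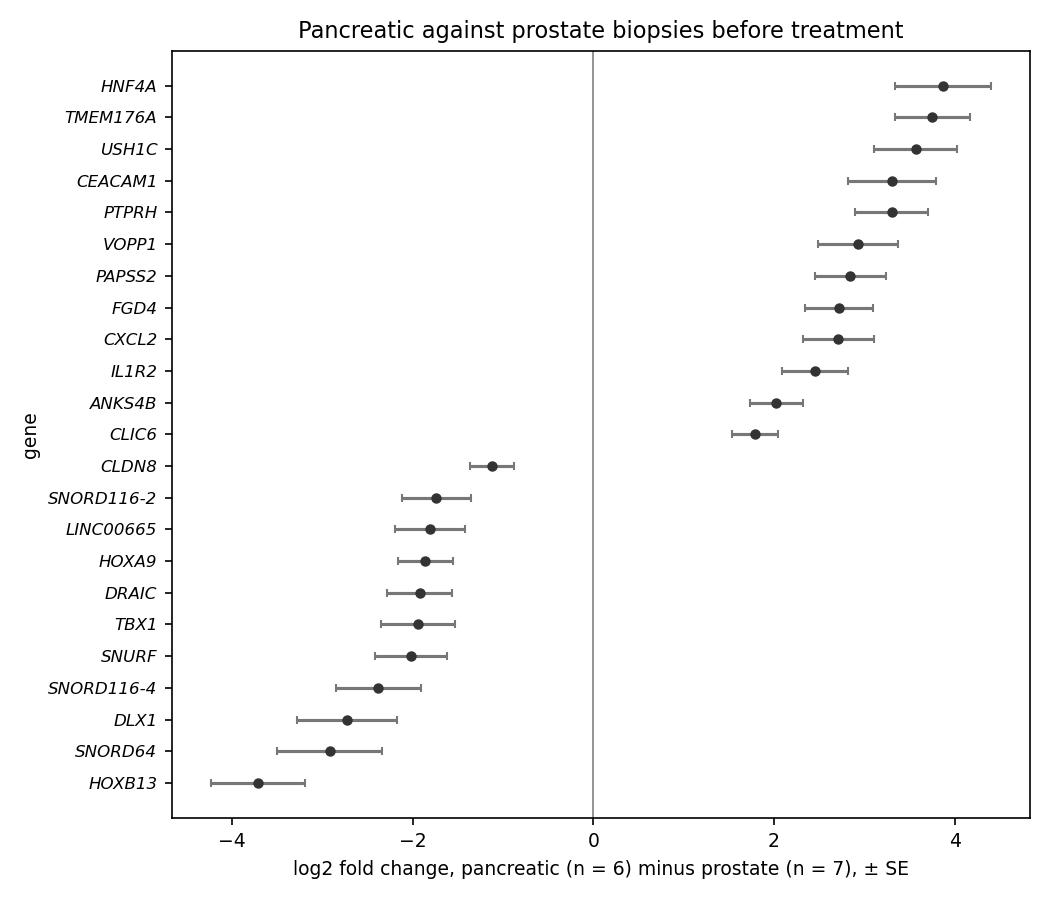
Log2 fold change of log2(FPKM + 1), pancreatic (n = 6) minus prostate (n = 7) libraries before treatment, with bars of 1 SE. The 23 genes are those named for the smallest p in each direction past the threshold. Among them HNF4A was highest at 3.87 and HOXB13 lowest at -3.71. Called genes named only as list members, such as CEACAM5 and KLK3, are not drawn.

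None of 24 lists passed a two-sided exact permutation test after adjustment, while 10 had an unadjusted p under 0.05 (smallest possible p 0.000583). That number was 5 with quantile normalization, and 3 each with protein-coding sum scaling, with scores relative to the median of all genes and without the ALB-high libraries. The prostate epithelium list differed by -3.43 (-3.72 relative to the median of all genes, exact p = 0.00874, adjusted p = 0.0699). Of its 12 members 3 were lower over all genes, among them HOXB13 and KLK3 (-6.52 ± 1.45), and 8 were when adjusted over the list alone. The immediate early stress list differed by 1.07 (0.77 relative to that median, exact p = 0.00525, adjusted p = 0.0699). Of its 10 measured members FOS (2.84 ± 0.48), ZFP36 (2.22 ± 0.45) and JUNB (2.02 ± 0.43) were higher over all genes, and 5 were when adjusted over the list alone. The p53 and DNA damage response list differed by 0.65 (0.35 relative to that median, exact p = 0.00816, adjusted p = 0.0699), with 0 of 18 members called. The gastrointestinal epithelium list differed by 2.86 (exact p = 0.0286, adjusted p = 0.0962), with the carcinoembryonic antigen gene CEACAM5 higher over all genes (5.60 ± 1.16). The type I interferon response list differed by 1.62 (exact p = 0.0239, adjusted p = 0.0962), with MX2 higher over all genes (2.79 ± 0.57) and 7 of 16 members higher when adjusted over the list alone. The hepatocyte list differed by 4.57 (exact p = 0.0414, adjusted p = 0.0993), with 0 of 10 measured members called and 6 higher when adjusted over the list alone. The T cell list differed by 1.04 (exact p = 0.0321, adjusted p = 0.0962) and the HIF hypoxia target list by 0.11 (-0.19 relative to the median of all genes, exact p = 0.773).

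The last comparison related hypoxia to T cell markers, since the drugs act on hypoxic tissue and on T cells. Over the 16 libraries before treatment the HIF hypoxia target and T cell scores had Pearson's r = -0.16 (permutation p = 0.549) and Spearman's rho = -0.07 (permutation p = 0.805). Within the 7 prostate libraries r was 0.52 and rho 0.36 (exact permutation p = 0.239 and 0.444), and within the 6 pancreatic libraries r was -0.51 and rho -0.09 (exact permutation p = 0.299 and 0.919). Without the 2 libraries farthest from the median hypoxia score, r was -0.18, 0.40 and 0.21 in these sets. The changes on treatment had r = -0.71 and rho = -0.68 over the 9 pairs (exact permutation p = 0.0323 and 0.0503, adjusted p = 0.129 and 0.201 over 4 relations). Without the 2 pairs farthest from the median hypoxia change r was -0.46. Those pairs were the lowest and the highest hypoxia change (-1.60 and 1.14). Leaving out both ends narrows the range and can lower r by itself, so this value cannot decide whether r rested on them. Leaving out 1 pair at a time gave r between -0.83 and -0.59. With quantile normalization r was -0.86 (exact permutation adjusted p = 0.0147). No tumour type had 6 pairs, so no r is given within a type.

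**Figure D4:**
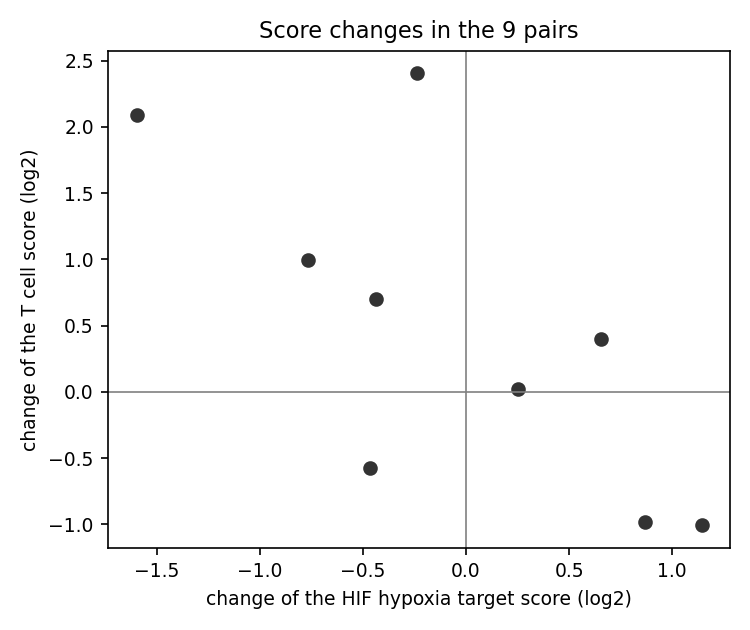
Change of the T cell score against change of the HIF hypoxia target score, both in log2(FPKM + 1), with 1 point for each of the 9 pairs. Pearson's r was -0.71, and -0.46 without the 2 pairs farthest from the median hypoxia change.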

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

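These values stood apart from the others of their group by Dixon's gap ratio, the gap to the nearest value divided by the whole range. Of 100 sets of values examined 10 were picked out, and chance picks about 1 in 20. In the 7 prostate libraries before treatment, 1 library had a low mitochondrially encoded score (7.74, nearest 11.78, ratio 0.753), 1 a low ribosomal protein score (5.14, nearest 7.12, ratio 0.687) and 1 a low number of protein-coding genes of at least 1 FPKM (8713, nearest 10571, ratio 0.613). The library with the low number of genes belonged to the 5 prostate pairs, so it was a baseline of the changes there. High values in the same group were seen for the hepatocyte score (7.29, nearest 1.06, ratio 0.868), the erythroid and blood score (12.48, nearest 5.79, ratio 0.78), the neutrophil and granulocytic myeloid score (4.13, nearest 1.78, ratio 0.653) and the T cell activation and checkpoint score (3.15, nearest 1.55, ratio 0.574). In the 6 pancreatic libraries before treatment, 1 had a high plasma cell score (6.53, nearest 3.94, ratio 0.659). Among the 9 pairs, 1 had a low change of the HLA class I presentation score (-3.70, nearest -0.44, ratio 0.54). Among the 5 prostate pairs, 1 had a low change of the neutrophil and granulocytic myeloid score (-4.89, nearest 0.90, ratio 0.724).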

How the results depend on the processing

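Protein-coding sum scaling, the settings without the HOXB13-low or ALB-high libraries and leaving out pairs for the correlation were chosen after the data were seen. Over all 9 pairs and for the difference between tumour types, 0 genes were called by limma under every setting run, with and without the replicate block (145 to 1248 and 444 to 1682 at an unadjusted p under 0.05). In the prostate pairs the 37 calls became 61 with array weights and 65 with protein-coding sum scaling, of which 36 each were among the 37. They became 0 without the filter on low values (47607 genes tested), 0 without the replicate block, and 0 in the 3 pairs left without HOXB13 below 1 (6 libraries); the cause of the other moves was not tested. Leaving out 1 pair gave 12 to 26, and 3 of the 5 pairs moved the count by over 1.5 times. Of the 167 genes between pancreatic and prostate libraries, 11 were called without the filter, 56 with quantile normalization, 370 with array weights, 2 with all libraries and the replicate block as a random effect, 62 with protein-coding sum scaling and 19 without ALB-high libraries, and leaving out 1 library gave 29 to 325; each of the 7 prostate and 3 of the 6 pancreatic libraries moved the count by over 1.5 times. Of the list results, camera with the preset correlation called 10 lists over all pairs and 13 between pancreatic and prostate libraries, and 0 and 0 with an estimated correlation. In the prostate pairs camera called 13 and 1 (plasma cell), and for the difference in change 9 and 0; leaving out 1 library gave 0 to 3 between the tumour types, and no other setting of the exact tests called a list. In the prostate pairs 5 list values moved by over 1 SD: plasma cell to 3.47 (pseudocount 0.1), 2.16 (no filter) and 2.33 (protein-coding sum), CD8 to 2.21 (pseudocount 0.1) and p53 from 0.44 to -0.09 (protein-coding sum). For the score changes r was -0.86 with quantile normalization, where the adjusted p of 0.0147 passed, and the adjusted p lay between 0.0147 and 0.398 over the settings run; leaving out 1 pair gave -0.83 to -0.59, and 1 of the 9 took it past the threshold (adjusted p = 0.0442). A turn of direction was counted for a named gene only if it was called in either setting or if both values exceeded 1 SE, so sign changes of genes near no change were not counted. Those counted, all in the 3 prostate pairs left without HOXB13 below 1 and none called, were DCN (-0.78) and TMPRSS2 (0.75). Of the other named genes in the prostate pairs, 71 values lost and 6 gained a call while keeping direction, and between the tumour types 184 lost and 27 gained one. Depth is unknown, so low genes such as CTLA4 and FOXP3 cannot be compared.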

Other observations

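The tests in this part, except the counts of other splits, were chosen after the results were seen. Gene groups not described above gave these values. Over the 9 pairs the macrophage list had a change of 0.83 ± 2.45 (SD, 6 of 9 pairs higher), the mitochondrially encoded list one of 0.58 ± 1.57, the erythroid and blood list one of -1.05 ± 3.60, the fibroblast and matrix list one of 0.33 ± 2.61 and the type I interferon response list one of 0.19 ± 1.90, none of which passed the exact permutation test. The lists with too few measured members were scored without a filter, and the B cell list had a change of -0.23 ± 1.86 and the neuroendocrine list one of -0.56 ± 1.38. Before treatment the neuroendocrine score was 2.39 ± 2.60 in the 6 pancreatic and 0.52 ± 0.38 in the 7 prostate libraries.

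Immunoglobulin genes rose in the prostate pairs: the median change of the 81 tested ones averaged 2.59 ± 0.36 (SD) over the 5 pairs, and leaving out any 1 pair gave no less than 2.46, which argues against 1 pair carrying it. With the filter on low values run on the 16 libraries before treatment of all tumour types, which took 82 genes, it was 2.55 ± 0.36. This argues against a rise made by filtering on the on-treatment libraries. Those 82 genes still passed a filter. Over all 325 without a filter the average was 0.12 ± 0.20 (3 of 5 pairs higher) and the mean over genes was 0.87. For the 81 tested genes the average was 2.42 ± 0.43 with protein-coding sum scaling, which argues against scaling. In the 3 pairs whose hepatocyte score changed by less than 1 their median change was at least 2.29, which argues against liver tissue as the whole source. The 16 ways of swapping time points within pairs are too few for a share under 0.05; the real one gave 37 genes and the highest other 0. Treatment, time between biopsies and the site sampled stay open, as there were no untreated second biopsies, and more plasma cells in the biopsies on treatment is a hypothesis that these values may fit.

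More genes were higher than lower in the pancreatic libraries. With protein-coding sum scaling 51.6% of the calls were higher, against 85.0% without it, so the excess of higher genes may come from scaling between libraries. Without ALB-high libraries the median log2 fold change of the 142 higher genes was 2.18, against 2.30 in all, so their fold did not rest on those libraries. They were called on the same data, however, where genes high only in ALB-high libraries vary much within a group. Of the 10 measured hepatocyte members 0 were called. The test therefore cannot decide how far liver tissue contributed. The fall to 19 calls came with 9 of the 13 libraries. Of 100 splits of the libraries, drawn from 1716 possible, only the real one gave as many as 167 genes. Among the others 7 called any gene, at most 29, which argues against a chance split but does not exclude it. Tumour type itself stays open, untested.

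Of the 25 genes lower in the pancreatic libraries, 8 lay on chromosome 15 between 24823637 and 25419462, from SNRPN to the end of SNHG14, the host transcript of the SNORD116 snoRNAs. Of the 31 tested genes there, 31 were lower and 28, or 90.3%, were lower by more than 1 (median -1.82), which cannot separate 1 long transcript read as several genes from genes regulated together. Short RNAs held 50.3 ± 15.7% (SD) of FPKM in the pancreatic and 64.2 ± 15.6% in the prostate libraries. The 865 tested short RNAs outside the locus had a median of -0.27 (quartiles -0.60 and 0.09). The 213 snoRNAs among them, of which 176 were lower, had one of -0.40 (quartiles -0.76 and -0.11). The 8 genes of the locus that are not short RNAs had a median of -2.09. These values argue against fewer short RNAs as the whole cause. Whether the locus differs by tumour type or by cell content was not tested. For all 9 pairs and for the difference between tumour types the real count was 0, so 100 of 100 splits gave as many by construction, and the splits decide nothing there. Among the other splits over all pairs 2 called any gene, at most 180, and for the difference 1 did, with 15. A structure among the libraries was not tested.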
